A study of Mus musculus with 25 samples.

How the data were processed

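Expression was measured in brain, liver, gonadal white adipose tissue and gastrocnemius muscle of the congenic mouse strain B6.C-D7Mit353 and of its background strain C57BL/6J, called B6 here. Per the labels' protocols, total RNA was extracted with TRIzol, amplified to digoxigenin-labelled cRNA and read by chemiluminescence on 1-colour Applied Biosystems arrays, with 1 sample per array. The series design names biological triplicates of each strain in each tissue. A number in the liver, fat and muscle titles recurs across tissues and was taken to name the animal. The brain titles carry codes of another form, so each brain array was treated as an animal of its own. A B6 adipose array that the design text names among the livers was used as adipose, as its title and source label give it. The 25th array, congenic brain replicate 2, is not in the named triplicate and entered alternatives only. Its code differs in the last letter from that of congenic brain replicate 4, and the correlation of the pair over tested probes was r = 0.973, while a pair of B6 brain arrays reached 0.978.

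Each deposited array table holds 32996 probes with a Signal column, a signal to noise ratio and a flag. The deposited Signal is an intensity on a linear scale, per the file headers and its values, and the array software and any background step are not given in the sources used here. The deposited signal to noise ratio is a score for each probe, also per the file headers. The deposited series matrix holds log2 values. On each array these equal log2 of the Signal plus a constant that brings the median of all probes to 9.26, and they are blank exactly where the signal to noise ratio is below 3. The median of the filled values ran from 11.37 to 12.12. No Signal was 0 or negative, and probes with a ratio near 0 still had median signals of 138 to 399, so the Signal was treated as not background corrected.

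In each tissue, normexp background correction with an offset of 50, log2 and quantile normalization among the 6 arrays were applied with limma. Probes with a signal to noise ratio of at least 3 on at least 3 of the 6 arrays were tested. The strains were compared by limma's lmFit and eBayes with an intensity trend, with Benjamini-Hochberg adjustment over the probes of the tissue and a threshold of 0.05. Signed values are congenic minus B6. The effect averaged over tissues and the tissue by strain interaction came from a limma fit of 24 arrays with a mean for each tissue and strain and the title number as a random block, over probes that passed the filter in at least 2 tissues. The correlation within title numbers was estimated at -0.0976. Software was R 4.3.3 and limma 3.58.1. The p-values measure the spread between the arrays of these few animals, and the number of arrays limits the precision.

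Genes were named through the platform annotation, with symbols updated by Entrez identifier in the GRCm38.p6 gene table. Of the probes, 14401 had 1 gene, 247 had several and were not named, and 18348 are unnamed here. The gene table also gave each gene's chromosome and neighbours. The array files name no genome build, so no coordinates are printed. Where a gene had several probes, that of highest mean signal was used. A probe detected on no array of a strain has only a bound there, written "at least N-fold". This bound sets the brighter strain's mean against a mean for the dimmer strain. That mean takes, per array, the higher of the probe's own value and the lowest detected signal. For Rab27a, Hsf2, Stx6 and most other genes so written, the bound equals the fitted fold. It is then a point estimate with the error of the fit, and not a guaranteed minimum. For Rab27a and Cidec in gastrocnemius the fitted log2 differences were 2.94 ± 0.47 and 2.48 ± 0.64 (SE).

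Before the data were examined, 47 gene lists were fixed for pathways, cell types and neighbouring tissues, together with the tests, most alternatives and the rule for named genes. Lists with at least 5 tested genes were compared by limma's camera with a preset correlation of 0.01, adjusted over the lists of a tissue, in 85 tests. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. In a tissue with under 5 called genes the rule names the 10 genes of smallest unadjusted p, with values only. For the interaction it names the 10 of smallest p, and for a list past its test without a called member, the 3 of largest change.

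The test was tried on data simulated from the real means and spreads with 200 changed probes. These were 50 each at 1, 2, 3 and 4 log2 units, and probes were drawn independently. Of probes changed by 2 log2 units, 74% were recovered in brain, 56% in liver, 36% in gonadal fat and 66% in gastrocnemius. Of those changed by 1 log2 unit, 26%, 6%, 2% and 22% were recovered, in the same order. The fit averaged over tissues was simulated without the block on 10480 probes that passed the filter in every tissue, against 16451 in the real fit. In that simulation 82% and 98% of shared changes of 1 and 2 log2 units were recovered. The adjusted threshold is easier to reach with many large planted changes. All of these rates can therefore overstate recovery where few probes differ. Unchanged probes made up 5 of 145 calls in brain, 8 of 126 in liver, 5 of 96 in gonadal fat, 4 of 131 in gastrocnemius and 20 of 210 in the averaged fit. Other alternatives were median scaling, the series matrix values, other detection filters, log2 of the Signal plus 1, no intensity trend, array weights, a fit over all tissues with a shared variance, and leaving out each array in turn. The planned normexp alternative became the main setting once the Signal proved uncorrected, and a planned block for slide or scan was not run because the files used here give neither. Setting spots with flag 0 missing, 165 to 626 per array, was an alternative chosen after seeing the data. The planned scan of called genes along the chromosomes had no calls to count and was replaced, after seeing the data, by a scan of ranked p-values.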

Results

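The series holds 25 arrays, of which 24 form the comparisons, with 3 congenic and 3 B6 arrays in each of 4 tissues. B6.C-D7Mit353 is a congenic strain, named for a marker on chromosome 7 and described in its labels as lean and homozygous. The comparisons ask which transcripts differ between the strains in tissues of energy balance. Between 13115 and 18236 probes were detected per array, 39.7% to 55.3% of those present. A value written "at least" some fold below is the bound defined above, an estimate with error and not a guaranteed minimum. Correlations between the arrays of a tissue ran from 0.944 to 0.978 in brain, 0.917 to 0.963 in liver, 0.826 to 0.965 in gonadal fat and 0.937 to 0.971 in gastrocnemius, across probes, which are not independent. Their means within and between strains were 0.962 and 0.959 in brain and 0.904 and 0.901 in gonadal fat. In liver these were 0.945 and 0.947, and in gastrocnemius 0.947 and 0.949, so no higher within strains. Of the Y-linked transcripts, Eif2s3y was detected on 25 of the 25 arrays, Uty on 14 and Kdm5d on 4.

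In brain the smallest p belonged to Pla2g4a, a cytosolic phospholipase. Its log2 signal was 11.69 ± 0.67 in the congenic and 13.55 ± 0.23 in B6 (SD, n = 3 each), a log2 difference of -1.87 ± 0.29 (SE). S100a8 and S100a9, the calprotectin subunits abundant in granulocytes, had the widest differences, at -3.55 ± 0.82 and -2.91 ± 0.65. S100a8 was detected on 2 of 3 congenic arrays, and B6 replicate 1 lay at 10.52 for it against 14.01 and 13.90 on the other B6 arrays. Myo7a, an unconventional myosin gene on chromosome 7, was at -2.29 ± 0.42 and was detected on 1 of 3 congenic and 3 of 3 B6 arrays. Rnf169, also on chromosome 7, was at -0.92 ± 0.21, and the lectin gene Itln1 at -1.46 ± 0.25. Ifi205, an interferon-inducible gene, was detected on no congenic array and was at least 6.40-fold lower there. Hsf2, a heat shock transcription factor gene, was likewise at least 5.88-fold lower. Rsrc2, at 0.87 ± 0.16, and Abca2, a lipid transporter gene, at 0.73 ± 0.15, were the named genes with higher congenic values. Congenic replicates 1 and 3 detected 16345 and 15843 probes, against 17353 on congenic replicate 4 and 17862, 17925 and 17049 in B6. Whether this lower detection bears on the lower congenic values was not tested.

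No gene list passed the set test in brain. Of 14 cholesterol synthesis genes, 13 had lower congenic values, with a median of -0.20 (camera, adjusted p = 0.142). Of 12 macrophage genes, 9 had lower values, with a median of -0.24 (adjusted p = 0.185), and 3 passed when adjusted over the list alone, against 0 over all probes. The other brain lists had adjusted p-values from 0.185 to 0.998. The median, mean and test differed in sign for the cerebellum, oxidative phosphorylation, feeding neuropeptide and thalamus lists. Limma tested 16908 brain probes and called 0, with 1632 at an unadjusted p under 0.05, where 845.4 are expected by chance, and a lowest adjusted p of 0.336. Congenic and B6 arrays did not overlap for 15.4% of tested probes, against 10% by chance. Without B6 replicate 1 limma called 2, S100a8 at -4.67 (adjusted p = 0.0154) and S100a9 at -3.96 (adjusted p = 5.4e-05). Without congenic replicate 4 it called 2, Pla2g4a at -2.22 (adjusted p = 0.0292) and an unnamed probe. Without congenic replicate 3 or B6 replicate 3, 1 list passed.

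In liver the smallest p of a probe with a gene name belonged to Ppargc1a, a coactivator of gluconeogenic genes. Its log2 signal was 13.01 ± 0.30 in the congenic and 11.04 ± 0.54 in B6 (SD, n = 3 each), a 3.91-fold higher value with a log2 difference of 1.97 ± 0.32 (SE). Noct, a gene with a daily rhythm in liver, was at 1.82 ± 0.36. Tat, the amino acid catabolic enzyme tyrosine aminotransferase, was at 1.15 ± 0.26. Cd1d2, an antigen-presenting molecule, was at 1.78 ± 0.32 and was detected on 2 of 3 B6 arrays, and Lyve1, a marker of sinusoidal endothelium, at 1.22 ± 0.27. The syntaxin gene Stx6 was detected on no B6 array and was at least 4.72-fold higher in the congenic. Lower congenic values were those of Rnf43, a ubiquitin ligase of the Wnt pathway, at -1.33 ± 0.24, the laminin gene Lamb3 at -1.41 ± 0.27, the pantetheinase gene Vnn1 at -1.09 ± 0.25 and the immediate early gene Egr1 at -1.51 ± 0.37. Limma tested 13956 liver probes and called 0, with 456 at an unadjusted p under 0.05, where 697.8 are expected, and a lowest adjusted p of 0.261 for an unnamed probe. The strains did not overlap for 6.96% of tested probes, against 10% by chance.

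Of 22 lists tested in liver, 5 passed camera. Fatty acid oxidation genes shifted downward, with 18 of 22 lower and a median of -0.32 (adjusted p = 6.3e-05, and adjusted p = 0.148 with an estimated correlation). Beside Vnn1, the largest differences were those of Ehhadh, a peroxisomal enzyme, at -0.97 ± 0.35 and of the hormone gene Fgf21 at -0.72 ± 0.43. In this list 1 member passed when adjusted over the list alone and 0 over all probes, and fry also passed it (adjusted p = 3.07e-04). Gluconeogenesis and glycogen genes shifted upward, with 9 of 14 higher and a median of 0.26 (adjusted p = 2.09e-04, and adjusted p = 0.235 with an estimated correlation). Ppargc1a and Tat belong to this list, and Igfbp1, an insulin-repressed binding protein gene, was at 0.91 ± 0.55. Adjusted over the list alone, 4 of its members passed, against 0 over all probes. Cholesterol synthesis genes shifted downward, with 13 of 14 lower and a median of -0.27 (adjusted p = 0.0109, and adjusted p = 0.711 with an estimated correlation). Insig1 was at -0.67 ± 0.37, Fdft1 at -0.56 ± 0.30 and Hmgcs1 at -0.47 ± 0.24, and 0 members passed when adjusted over the list alone. Without congenic replicate 1 the adjusted p was 0.0558 for the gluconeogenesis list, and for cholesterol synthesis it was 0.157, 0.0718, 0.105 and 0.452 without congenic replicates 1 and 3 and B6 replicates 1 and 2. The gluconeogenesis median was 0.42, 0.14 and 0.46 without congenic replicates 1 and 3 and B6 replicate 2, and that of cholesterol synthesis -0.13 and -0.51 without B6 replicates 2 and 3.

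The cholangiocyte and pancreas list shifted upward in congenic liver, with 9 of 9 genes higher and a median of 2.37 (adjusted p = 7.3e-05, and adjusted p = 0.711 with an estimated correlation). The pancreatic enzyme genes Ctrb1, Cel and Cpa1 were at 3.68 ± 1.97, 2.97 ± 1.39 and 2.67 ± 2.03. Ctrb1 was detected on 2 of 3 arrays of each strain and Cpa1 on 2 of 3 congenic arrays. Epcam, an epithelial marker, was detected on no B6 array and was at least 5.16-fold higher in the congenic, and with Epcam at this bound the list median is 2.37 too. Adjusted over the list alone 1 member passed, and 0 over all probes. The list lay 5.10 log2 units above the mean of the 6 arrays in congenic replicate 2, at 1.04 in congenic replicate 3 and at -2.91 in congenic replicate 1. Macrophage genes also shifted upward, with 11 of 12 higher and a median of 0.30 (adjusted p = 0.00799, and adjusted p = 0.711 with an estimated correlation). Cd163 was at 0.73 ± 0.33 and Cd14 at 0.64 ± 0.45, while Adgre1 was at -0.62 ± 0.71, and 0 members passed when adjusted over the list alone. Cd14 was detected on 2 of 3 B6 arrays and Adgre1 on 2 of 3 arrays of each strain. The macrophage list was also highest in congenic replicate 2, at 0.82, where the gluconeogenesis list lay at -0.04 and the cholesterol synthesis list at 0.03. Without congenic replicate 2, the pancreas list had a median of 0.21 (adjusted p = 0.442) and the macrophage list -0.029 (adjusted p = 0.975). Without B6 replicate 1 the macrophage list had an adjusted p of 0.169, and without congenic replicate 1 the medians were 4.84 for the pancreas list and 0.75 for macrophage genes. The other liver lists had adjusted p-values from 0.112 to 0.948, and the median, mean and test differed in sign for the interferon, lymphocyte and fatty acid synthesis lists.

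In gonadal fat the smallest p of a probe with a gene name belonged to Tomm7, of the mitochondrial import channel. Its log2 signal was 16.64 ± 0.28 in the congenic and 15.59 ± 0.17 in B6 (SD, n = 3 each), a 2.07-fold higher value. Ndufa5, Ndufa2 and Ndufa3, subunits of respiratory complex I, were at log2 differences of 1.07 ± 0.27, 1.01 ± 0.26 and 0.89 ± 0.23 (SE), and Romo1, a mitochondrial membrane protein gene, at 0.87 ± 0.22. The protease inhibitor gene Slpi was at 1.25 ± 0.29 and the ATP-gated channel gene P2rx1, detected on 2 of 3 B6 arrays, at 1.75 ± 0.47. Rasd1, a glucocorticoid-induced Ras gene, was at -1.40 ± 0.34 and the gastrin gene Gast, detected on 1 of 3 congenic arrays, at -1.94 ± 0.50. Slc16a11, a transporter gene, was detected on no congenic array and was at least 4.93-fold lower there. Limma tested 17624 probes and called 0, with 609 at an unadjusted p under 0.05, where 881.2 are expected, and a lowest adjusted p of 0.909. The strains did not overlap for 8.10% of tested probes, against 10% by chance. Congenic replicate 2 had a mean correlation of 0.950 with the B6 arrays and 0.853 with the other congenic arrays. These means were 0.850 and 0.863 for congenic replicate 1 and 0.904 and 0.890 for congenic replicate 3. Without congenic replicate 2, the congenic array most like B6, limma called 275, 64 higher and 211 lower. Of these, 189 lay farthest from B6 in congenic replicate 1, which is 1 of the 2 congenic arrays left and has low values of reproductive tract genes. Among the lower were the epididymal genes Defb35 at -5.41 (adjusted p = 0.0441), Ros1 at -5.13 (adjusted p = 0.0338), Lcn5 at -4.67 (adjusted p = 0.0449) and Spag11a at -4.63 (adjusted p = 0.0443), while Svs2, of seminal vesicle, was at 6.06 (adjusted p = 0.0338). Of the named genes, Rasd1 was at -1.74 (adjusted p = 0.0373), Ndufa5 at 1.32 (adjusted p = 0.0466) and Ndufa2 at 1.25 (adjusted p = 0.0479).

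Of 20 lists tested in gonadal fat, 6 passed camera, each with an adjusted p = 0.666 with an estimated correlation and with 0 members past the test over all probes or adjusted over the list alone. Oxidative phosphorylation genes shifted upward, with 21 of 28 higher and a median of 0.40 (adjusted p = 4.4e-06). Ndufb3 was at 1.29 ± 0.40 and Cox5b at 1.06 ± 0.29. The list lay at 0.43 above the mean of the 6 arrays in congenic replicates 1 and 3 and at -0.28 in congenic replicate 2. Genes of the heat shock and unfolded protein response shifted downward, with 10 of 12 lower and a median of -0.44 (adjusted p = 0.0167). Its members Pdia6, Pdia4 and Hsp90b1, chaperones of the endoplasmic reticulum, were at -1.22 ± 0.45, -1.19 ± 0.52 and -1.08 ± 0.57. Cholesterol synthesis genes shifted downward, with 10 of 14 lower and a median of -0.49 (adjusted p = 0.0365), and Sqle, Msmo1 and Tm7sf2 were at -1.18 ± 0.58, -1.10 ± 0.55 and -0.98 ± 0.56. Macrophage genes shifted upward, with 13 of 16 higher and a median of 0.34 (adjusted p = 0.0225), and the chemokine gene Ccl2, detected on 2 of 3 B6 arrays, was at 1.28 ± 0.64, Msr1 at 1.02 ± 0.49 and Cd163 at 0.75 ± 0.32. Without congenic replicate 2 the medians were 0.62 for oxidative phosphorylation, -0.71 for the unfolded protein response, -0.74 for cholesterol synthesis and 0.79 for macrophage genes. For oxidative phosphorylation the median was 0.23 without congenic replicate 3. Without congenic replicate 1 the medians were -0.22 for the unfolded protein response, -0.31 for cholesterol synthesis and 0.12 for macrophage genes. For macrophage genes the medians were also 0.14 and 0.53 without congenic replicate 3 and B6 replicate 1, and for cholesterol synthesis -0.15 without B6 replicate 3.

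Markers of the male reproductive tract had the widest differences in gonadal fat. The testis and epididymis list shifted downward, with 13 of 14 genes lower and a median of -1.93 (adjusted p = 0.0107). The epididymal genes Gpx5, Rnase10 and Lcn5 were at -3.82 ± 2.19, -3.67 ± 2.77 and -3.11 ± 1.30, with Rnase10 detected on 2 of 3 congenic arrays. In congenic replicate 1 the list lay at -4.79 against the mean of the 6 arrays, and 13 of its 14 genes had their lowest value there. Genes of proteins secreted by hepatocytes shifted upward, with 6 of 6 higher and a median of 0.67 (adjusted p = 0.0451). Apoc3, Alb and Ttr were at 2.33 ± 1.58, 1.81 ± 0.83 and 0.78 ± 0.72, and the list was highest on the same array, at 1.49. Apoc3 was detected on 2 of 3 congenic and 1 of 3 B6 arrays, and Alb on 2 of 3 B6 arrays. Without congenic replicate 1, 1 list passed, and the testis and epididymis list had a median of 0.016 (adjusted p = 0.406). The same exclusion gave the unfolded protein response list an adjusted p of 0.180, macrophage genes 0.290, cholesterol synthesis 0.270 and hepatocyte proteins 0.827, with a median of -0.023. Macrophage genes also had 0.175, 0.0619 and 0.0815 without congenic replicate 3 and B6 replicates 2 and 3, cholesterol synthesis 0.0706, 0.105 and 0.0834 without congenic replicate 3 and B6 replicates 1 and 3, and hepatocyte proteins 0.129 and 0.0635 without B6 replicates 1 and 2. Without congenic replicate 2, 11 lists passed, with medians of -3.92 for testis and epididymis and 1.11 for hepatocyte proteins. The other fat lists had adjusted p-values from 0.0515 to 0.978, and the median, mean and test differed in sign for the fatty acid synthesis, circadian clock and mesothelium lists.

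In gastrocnemius the smallest p belonged to Rab27a, a vesicle transport gene, which was detected on no B6 array. Its bound of 7.67-fold higher in the congenic equals the fitted fold, with a log2 difference of 2.94 ± 0.47 (SE). Cyp2e1, a cytochrome P450 gene, had a log2 signal of 15.03 ± 0.74 in the congenic and 12.62 ± 0.55 in B6 (SD, n = 3 each), a 5.29-fold higher value with a log2 difference of 2.40 ± 0.39 (SE). Cidec, a lipid droplet protein gene, Cdo1, of cysteine breakdown, Gsta3, a glutathione transferase gene, and H2-Q10, of the major histocompatibility complex, were detected on no B6 array and were at least 5.59-fold, 4.79-fold, 4.42-fold and 4.73-fold higher. Mgst1, a microsomal glutathione transferase gene, was at 0.78 ± 0.21. In B6 gonadal fat, normalized apart, log2 signals were 20.13 for Cyp2e1, 17.18 for Mgst1, 17.05 for Cdo1, 16.61 for Cidec and 15.59 for Gsta3, with strain differences there of 0.04 ± 0.35, 0.52 ± 0.41, -0.29 ± 0.24, 0.04 ± 0.55 and 0.61 ± 0.41. Cyp2e1, Gsta3, Mgst1 and Cdo1 were also bright in B6 liver, at 20.85, 18.15, 19.57 and 17.51. H2-Q10 was at 12.88 in B6 gonadal fat and 19.79 in B6 liver, and Rab27a at 8.42 in B6 gonadal fat, detected on 1 of 3 arrays. Ppargc1b, a coactivator of mitochondrial genes, was at -0.84 ± 0.19, Nexn, of the sarcomere, at -0.70 ± 0.18 and Commd9 at -1.07 ± 0.27. Limma tested 13252 probes and called 0, with 373 at an unadjusted p under 0.05, where 662.6 are expected, and a lowest adjusted p of 0.996. The strains did not overlap for 7.76% of tested probes, against 10% by chance.

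Of 19 lists tested in gastrocnemius, 3 passed camera, each with an adjusted p = 0.835 with an estimated correlation and with 0 members past the test over all probes or adjusted over the list alone. Extracellular matrix genes shifted downward, with 16 of 18 lower and a median of -0.56 (adjusted p = 1.8e-04). Col6a2, Sparc and Postn were at -1.27 ± 0.59, -1.06 ± 0.54 and -0.98 ± 1.27, with Col6a2 detected on 2 of 3 congenic and Postn on 2 of 3 B6 arrays. The list lay at 1.41 above the mean of the 6 arrays in B6 replicate 2 and between -0.41 and -0.07 in the others, and without that array its median was 0.018 (adjusted p = 0.833). On the same array the macrophage list lay at 1.77 and the cell cycle list at 1.41, with the other arrays at 0.15 or below for both. Adipocyte identity and lipid storage genes shifted upward, with 16 of 20 higher and a median of 0.37 (adjusted p = 4.3e-04). Pck1 was at 2.31 ± 0.70 and the lipid droplet gene Plin1, detected on 2 of 3 B6 arrays, at 1.57 ± 0.53, beside the bound for Cidec, which leaves the list median at 0.37. This list was highest in congenic replicate 2, at 0.79, and without that array its adjusted p was 0.123. The heat shock and unfolded protein response list shifted downward, with 7 of 11 lower and a median of -0.41 (adjusted p = 0.0481), and Sdf2l1, Pdia4 and Pdia6 were at -1.52 ± 0.55, -0.85 ± 0.42 and -0.61 ± 0.42, with Sdf2l1 detected on 2 of 3 congenic arrays. Without B6 replicate 2 its adjusted p was 0.316, and without congenic replicates 2 and 3 and B6 replicate 3 it was 0.123, 0.0776 and 0.0887. Its median was -0.071 without B6 replicate 2 and -0.26 without congenic replicate 3. The adipocyte median was 0.24 without B6 replicate 1, and that of extracellular matrix -1.003 without B6 replicate 3. Without congenic replicate 3, B6 replicate 1 and B6 replicate 3, in turn, 5, 6 and 7 lists passed. The other gastrocnemius lists had adjusted p-values from 0.0535 to 0.952, and the median, mean and test differed in sign for the fast fibre, atrophy and glycolysis lists. No list passed with an estimated correlation in any tissue.

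**Figure D1:**
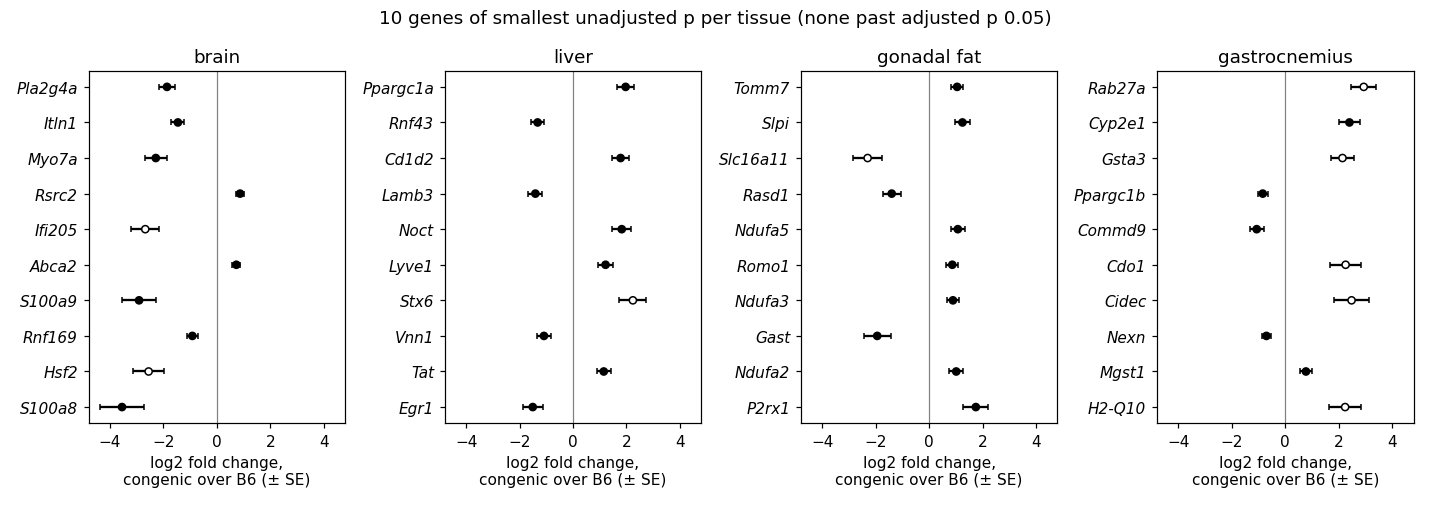
Log2 fold change, congenic over B6, with its standard error for the 10 named genes of smallest unadjusted p in each of the 4 tissues (3 arrays per strain). Open circles mark genes detected on no array of a strain, whose fitted value stands beside a bound only, and no gene passed the adjusted threshold.

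**Figure D2:**
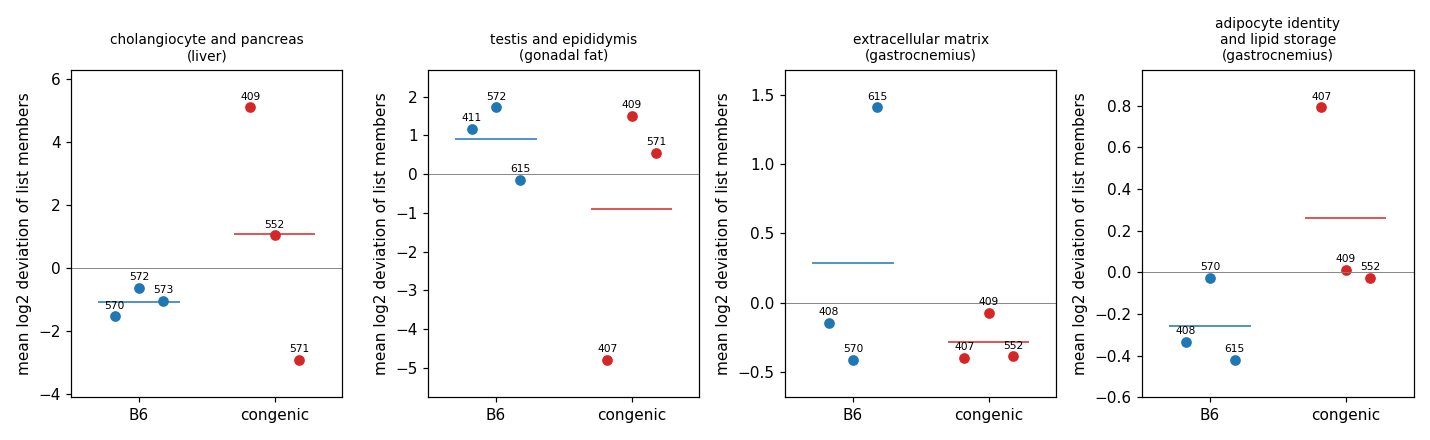
Mean log2 deviation of the members of 4 gene lists from the mean of the 6 arrays of a tissue, as a point per array labelled by its title number, with a line at each strain's mean. The pancreas list reached 5.10 in congenic liver replicate 2, the epididymis list -4.79 in congenic fat replicate 1, the extracellular matrix list 1.41 in B6 muscle replicate 2 and the adipocyte list 0.79 in congenic muscle replicate 2.

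The effect averaged over tissues asks for differences that a donor segment, present in every tissue, would leave in all of them. Myo7a had the smallest p, with an averaged log2 difference of -1.09 ± 0.21 (limma, unadjusted p = 3.11e-05, adjusted p = 0.512). Its fitted values were -2.29 in brain, -0.24 in liver and 0.01 in gonadal fat, and in gastrocnemius no congenic array detected it and it was at least 3.53-fold lower there. Noct was at 0.76 ± 0.17, with higher fitted congenic values in all 4 tissues. Rab27a, which passed the detection filter in gonadal fat and gastrocnemius alone, was at 1.48 ± 0.33. Its average takes in fitted values of 0.93 in brain and 1.26 in liver, where it failed that filter. It also takes in 2.99 in gastrocnemius, where no B6 array detected it, beside 0.73 in gonadal fat. Dusp8 and Prc1, further genes of chromosome 7, were at 0.56 ± 0.13 and -1.19 ± 0.30. Prc1 passed the detection filter in brain and gonadal fat alone, no congenic brain array detected it, and its average takes in fitted values of -0.93 in liver and -2.02 in gastrocnemius, beside -0.25 in gonadal fat. These genes were chosen after their values were seen, since the rule names none here. Limma tested 16451 probes and called 0, with 1073 at an unadjusted p under 0.05, where 822.55 are expected.

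The interaction asks whether the strain difference itself differs between tissues. Pgap4, of membrane anchor synthesis, had the smallest p (limma, adjusted p = 0.285). In liver it was detected on no B6 array and was at least 2.84-fold higher in the congenic, against fitted values of -0.30, -0.39 and -0.05 in brain, gonadal fat and gastrocnemius. Ifi205 had the same adjusted p, with its low congenic value in brain, and for Cdo1, with its high congenic value in gastrocnemius, the adjusted p was 0.353. Rasd1 had fitted values of -1.41 in gonadal fat and 2.06 in gastrocnemius, where 1 of 3 B6 arrays detected it (adjusted p = 0.771). Retnla, a resistin-like gene, was detected on no congenic brain array and was at least 4.65-fold lower there, and had a fitted value of 0.90 in gonadal fat (adjusted p = 0.749). Gsta3, Mnd1, Epn3, Pptc7 and Stx6 complete the 10 genes of smallest p, with adjusted p-values from 0.749 to 0.865. Limma called 0 of the 16451 probes, with 764 at an unadjusted p under 0.05. After quantile normalization over all 24 arrays, Pgap4 alone passed (adjusted p = 0.0421), and the lowest adjusted p of the other alternatives ran from 0.113 to 1.00.

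The donor segment is named for a marker on chromosome 7, which raises the question of whether differences gather there. With 0 calls in any tissue, the planned test of called probes had nothing to count. At an unadjusted p under 0.05, chromosome 7 held 65 brain probes against 66.4 expected from its share of tested probes (Fisher's exact test, two-sided p = 0.893), 23 against 19.8 in liver (p = 0.474), 31 against 26.6 in gonadal fat (p = 0.355), 17 against 16.1 in gastrocnemius (p = 0.792) and 56 against 49.4 in the averaged effect (p = 0.318), and of these chromosome 7 counts the lowest adjusted p over the chromosomes was 0.587, in gonadal fat. At an unadjusted p under 0.001, Myo7a and Rnf169 were the brain genes of chromosome 7 (2 probes against 0.93 expected, exact p = 0.237) and Cyp2e1, which had the bright signals in gonadal fat and liver given above, the gastrocnemius gene (1 against 0.24, exact p = 0.221). In the averaged effect, Myo7a, Dusp8 and Prc1 lay there, the last with the detection limit given above. These were 3 against 0.958 expected (exact p = 0.0647, adjusted p = 0.680 over the chromosomes). At the same cut liver had 0 on chromosome 7 against 0.39 expected, and gonadal fat had 0 on any chromosome.

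No probe was called in any pair of tissues, since limma called 0 in each. Across probes, which are not independent, the Pearson correlation of log2 fold changes was 0.158 between liver and gonadal fat, -0.061 between brain and liver, -0.064 between brain and gastrocnemius and 0.056 between gonadal fat and gastrocnemius, and it was -0.00324 between brain and gonadal fat and -1.26e-04 between liver and gastrocnemius. Expected numbers of shared probes assume independent tissues, while title numbers recur between liver, gonadal fat and gastrocnemius, so agreement above them can come from shared animals. At an unadjusted p under 0.05, liver and gonadal fat shared 14 probes of the same sign, against 6.52 expected, and 2 of opposite sign, against 6.34. Brain and liver shared 10 of the same sign, against 16.1 expected, and 32 of opposite sign, against 16.3. Brain and gonadal fat shared 36 of the same sign, against 22.6 expected, and 23 of opposite sign, against 24.2. Brain and gastrocnemius shared 8 of the same sign, against 15.9 expected, and 28 of opposite sign, against 15.5. The pairs of gastrocnemius with liver and with gonadal fat shared 5 and 6 of the same sign, against 3.27 and 5.62 expected, and 4 and 6 of opposite sign, against 3.31 and 5.80.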

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

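The counts of calls over other splits of the arrays were planned, while the counts of unadjusted p-values over splits and the tests of epididymal tissue, array sensitivity, adipose tissue in muscle, splits that keep title numbers together and a shift of dim transcripts were chosen only after the results were seen.

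Gene lists past camera in some tissue were compared between tissues by camera on the differences of the strain effects. Of 27 differences 13 passed, none of them with an estimated correlation. Pairs of tissues were tested only where the list had passed in either on these same arrays, which favours differences. Title numbers shared between tissues were not blocked. The adjusted p-values are therefore no independent test of tissue specificity. The fatty acid oxidation list lay lower in liver than in gonadal fat by a median difference of -0.35 (adjusted p = 0.00269) and than in gastrocnemius by -0.34 (adjusted p = 5.61e-04). The oxidative phosphorylation list had differences of -0.35 for brain and -0.30 for liver, each minus gonadal fat, and of 0.26 for gonadal fat minus gastrocnemius. Its fat median depended on the array left out, and congenic fat replicate 2 lay below the array mean, as given above. The macrophage list differed by -0.58 for brain minus liver, -0.41 for brain minus gonadal fat and 0.66 for liver minus gastrocnemius. Its liver median was -0.029 without congenic replicate 2, its fat median 0.12 without congenic replicate 1, and its muscle value 1.77 in B6 replicate 2. The extracellular matrix list differed by 0.53, 0.40 and 0.87 for brain, liver and gonadal fat, each minus gastrocnemius, where without B6 replicate 2 its median was 0.018, so these differences depend on 1 muscle array. The heat shock and unfolded protein response list differed by 0.40 for brain minus gonadal fat, and the hepatocyte protein list by -0.68 for liver minus gonadal fat, where without congenic replicate 1 their medians were -0.22 and -0.023. Among 12 measures over the 4 congenic brain arrays, 0 had an outlying array by Dixon's ratio, the highest being 0.774 for Abca2. With 4 arrays this test can flag only an extreme value, so it does not exclude an outlying array. It was not run in the other tissues.

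Testis and epididymis genes were lower in congenic gonadal fat, and congenic replicate 1 had the lowest value for 13 of 14 of them, by a median of 4.24 below the next lowest array. That array had the fewest detected probes in gonadal fat (15710, the others 17542 to 18236). It also had the lowest median Signal (373.9, the other congenic arrays 538.65 and 660.1, B6 743.55 to 951.8). Lower sensitivity as the whole cause is argued against by other probes as bright as the list's genes on the other 5 arrays. In unnormalized log2 Signal these lay there at a median of -0.81 (by gene, -0.89 to -0.50), while the list's genes lay at -6.51, and at most 7.66% of the matched probes lay as low as their gene. Without that array the list median was 0.016, which is consistent with a different share of epididymis in 1 dissected sample. Congenic replicates 2 and 3 had list values of 1.51 and 0.54, above the mean of the 6 arrays. Apart from the list test, its alternatives and the single probes, no strain difference in epididymal genes was tested.

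The adipocyte list shifted upward in congenic gastrocnemius by camera, with 16 of 20 genes higher. With an estimated correlation its adjusted p was 0.835, and 0 of its members were called. Probes counted as enriched in a tissue where its B6 log2 signal lay over 4 units above that of each other tissue. In muscle 38 fat-enriched probes had a median log2 difference of 0.57, with 29 higher. There 163 brain-enriched probes had -0.016 and 44 liver-enriched probes 0.035, so these had no like shift. They were not matched to the fat-enriched probes for dimness in muscle, so a shift of dim transcripts is not excluded. The B6 muscle arrays served both to pick all these probes and in the comparison. In liver 35 fat-enriched probes had a median of 0.47, but there the strains overlapped. Array medians were 0.11, 0.44 and -0.24 in congenic liver replicates 1 to 3 and 0.028, -0.11 and -0.41 in B6. In brain 27 fat-enriched probes had -0.16. The fat-enriched median in muscle lay at 0.91 in congenic replicate 2, an array of the same title number as congenic fat replicate 1, and at 0.13 and 0.021 in the other congenic replicates, against -0.66, -0.086 and -0.40 in B6. More adipose tissue in the dissected congenic muscle is a candidate explanation, while lipid stored within muscle fibres and a strain difference in such transcripts stay open as untested alternatives.

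With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and a count of 0 is reached by any split. In brain the strain split called 0 probes and the highest other split 0, in 10 of 10 splits as many, and 0 lists against 6, in 10 of 10. In gastrocnemius the values were 0 probes against 0, in 10 of 10, and 3 lists against 10, in 10 of 10. In liver the strain split called 0 probes against 74 in the split that joins congenic replicate 1 with B6 replicates 2 and 3, in 10 of 10, and 5 lists against 7, in 5 of 10. In gonadal fat it called 0 probes against 102 in the split that joins congenic replicates 1 and 3 with B6 replicate 2, in 10 of 10, and 6 lists against 12, in 5 of 10. These splits of liver and gonadal fat may reflect a structure of the samples other than strain. Each was picked as the highest of the other splits, and such a structure was not tested. Over 100 splits within tissues, 100 called as many probes as the averaged effect (0, highest other 118) and 100 as many as the interaction (0, highest other 168), which a count of 0 fixes in advance and which therefore tests nothing. At an unadjusted p under 0.05, 32 of the 100 splits had as many probes as the averaged effect (1073, highest other 2283) and 51 as many as the interaction (764, highest other 2570). These splits are drawn apart in each tissue and so part arrays of the same title number. Of 100 splits that keep each title number on 1 side, 30 had as many for the averaged effect (highest other 1586) and 42 for the interaction (highest other 1705). Within tissues that count was 1632 in brain, the most of any split (highest other 1473), 456 in liver (2554, 5 of 10 splits as many), 609 in gonadal fat (2821, 5 of 10) and 373 in gastrocnemius (1466, 6 of 10). The brain splits that joined congenic replicates 1 and 3 with B6 replicates 2, 3 and 1 in turn had 1473, 1277 and 548. The lower detection on that congenic pair, given above, cannot be told apart from strain in the brain count.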

How the results depend on the processing

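The setting of spots with flag 0 missing and the fit without 4 arrays whose marker lists stand apart were chosen after seeing the data. No paired analysis was possible because congenic and B6 arrays share no title number within a tissue. Without the title number as a block, the averaged effect and the interaction still had 0 calls. Of 140 alternative values for the comparisons, which are counts, 111 stayed at 0 with the main count or within a set ratio of it, and 29 moved. Of 488 for single genes and lists, 428 were the same, 53 weaker, 6 stronger and 1 reversed. Of the 488, 348 were gene values. Among these 342 kept their direction and stayed uncalled, which is all that the same label means for a gene, and 6 were stronger. The 53 weaker values and the 1 reversed value were thus all list values. For genes named in a tissue the values cover median scaling, series matrix values, flag 0 spots set missing and each replicate left out. They do not cover the fit over all tissues or the exchange of brain replicates, under which further named genes passed, as given below. The cause was not tested, except that fewer arrays remain when a replicate is left out.

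Brain calls were 1 with congenic replicates 2 and 4 averaged (Itln1), 3 with replicate 2 in place of replicate 4 (Pla2g4a, Itln1 and an unnamed probe), 2 with 1 fit over all tissues (Ifi205 and an unnamed probe) and 0 to 2 without each replicate. Brain lists past camera were 1 with median scaling, 2 with no detection filter and 0 to 1 without each replicate. Liver calls were 3 with 1 fit over all tissues (Pgap4, Stx6 and an unnamed probe), and liver lists 0 with an estimated correlation, 1 with fry and 4 to 7 without each replicate. Gonadal fat calls ran from 0 to 275 without each replicate, and its lists were 0 with an estimated correlation, 0 with fry and 1 to 11 without each replicate. The median of the testis and epididymis list ran from -3.92 to 0.016 without each replicate, and reversed without congenic replicate 1. Medians of further lists changed sign where the direction of the set test did not, to -0.023 for hepatocyte proteins in gonadal fat without that array, -0.029 for macrophage genes in liver without congenic replicate 2 and 0.018 for extracellular matrix in gastrocnemius without B6 replicate 2. Gastrocnemius calls were 3 with 1 fit over all tissues (Ampd2, Cdo1 and Gsta3), and its lists 0 with an estimated correlation, 0 with fry, 6 with median scaling, 7 with no detection filter and 2 to 7 without each replicate. The interaction had 1 call with quantile normalization over all 24 arrays (Pgap4). On chromosome 7, 2 probes in brain, 1 in gastrocnemius and 3 averaged over tissues had an unadjusted p under 0.001.

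The averaged effect had 0 calls by limma under each alternative run, with lowest adjusted p-values from 0.102 to 0.812. Without the 4 arrays that stand apart it had 0 (lowest adjusted p = 0.288) and the interaction 0 (lowest adjusted p = 0.712). Series matrix values moved the median over all probes by 0.14 in liver and in gonadal fat. A block for slide or scan was not run, since the files used here give neither. Signal over background limits dim transcripts, since 39.7% to 55.3% of probes were detected per array. Median Signal on congenic arrays of gonadal fat was 373.9 to 660.1, below the 743.55 to 951.8 of B6. In liver it was 311.7 to 387.4 against 322.05 to 471.2, and in gastrocnemius 414.8 to 501.05 against 499.2 to 569.8. In brain it was 961.25 to 1172.55 against 1071.3 to 1232.25. Array brightness thus cannot be told apart from strain in gonadal fat, while the strains overlapped elsewhere.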

Other observations

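The scans along the chromosomes and each test on chromosome 7 given here were chosen only after results were seen. A scan of called genes was planned and had none to count. The mean squared z in windows of 20 neighbouring genes was then tried in each tissue, in 4 scans, and its top window in brain, Nars2 to Ppme1 on chromosome 7, was reached in a share of 0.0511 of shuffled gene orders. A rank-based score replaced it, with the tissues also pooled and with windows of 10, 20 and 40 genes, in 18 scans. Neighbours follow the GRCm38.p6 assembly.

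Genes of chromosome 7 from Nars2 to Rnf169 had low p-values together. In brain, Myo7a was at -2.29 ± 0.42, Rnf169 at -0.92 ± 0.21, Slco2b1 at -0.81 ± 0.25, Nars2 at 0.87 ± 0.30 and Thrsp, a lipogenic gene, at 0.61 ± 0.18. In liver Thrsp was at 1.43 ± 0.50, the aquaporin gene Aqp11 at 1.14 ± 0.36 and Map6, detected on 1 of 3 congenic arrays, at -1.64 ± 0.73. In gonadal fat Ndufc2 was at 0.78 ± 0.24 and Kctd14, detected on 1 of 3 congenic arrays, at -2.20 ± 0.85. In gastrocnemius Serpinh1 was at -1.37 ± 0.53, and Map6 and Myo7a were detected on no congenic array and were at least 3.25-fold and 3.53-fold lower. None passed adjustment over all probes. These are the 13 of 68 values for the 20 genes with an unadjusted p under 0.05, 5 higher in the congenic and 8 lower, in a window that was itself chosen for low p-values. Among these, the strains overlapped for Serpinh1, with an SD of 1.10 in B6, and for Kctd14, with an SD of 1.81 in the congenic.

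Pooled over tissues, windows of 20 genes had their top there, with 0.0153 of 10000 shuffled gene orders as high. With windows of 10 and 40 genes the top lay on chromosome 3, at 0.190 and 0.105, so chance placement along the genome stays open. In brain alone the shares were 0.0342 for 20 genes and 0.0227 for 40, both on chromosome 7, and 0.0718 for 10, on chromosome 3. Without brain the share was 0.732 for 20 genes, with the top window at Fam181b to Neu3, also on chromosome 7. Windows of 10 and 40 genes without brain had their top on chromosomes 1 and 10, at 0.407 and 0.695. In liver alone the top lay on chromosome 8 for 20 genes (0.214) and chromosome 3 for 10 and 40. In gonadal fat the top for 20 genes was Pgghg to Rplp2, other genes of chromosome 7 (0.322). For 10 and 40 it lay on chromosomes 18 and 13. In gastrocnemius it lay on chromosome 18 for 20 (0.481) and 40 genes, and for 10 at Myo7a to Ppme1 on chromosome 7 (0.332). Of 100 splits of the arrays within tissues, 2 had a chromosome 7 window as high as the pooled one (2.10, highest other 2.19). These 2 include the strain split, but 32 of the 100 had a window as high somewhere in the genome (highest other 2.53). Those splits part arrays of the same title number. Of 100 splits that keep each title number on 1 side, 1 had a chromosome 7 window as high, the strain split itself (highest other 2.05), and 19 a window as high somewhere in the genome (highest other 2.44). The window found in brain was matched by 7 of 9742 windows in the other tissues (0.0719%), a standing seen before it was tested. Neighbouring windows share most of their genes, so this share is not a significance level.

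The strain is named for a marker of chromosome 7, so a strain difference in genes near it may underlie the pattern, as a hypothesis found and tested on the same data. The marker's place among these genes was not used here. Probe sequences and donor variants were not used here, so donor variants under the probes cannot be told apart from expression differences for the 5 higher or the 8 lower values. Of the genes with lower values, 4 of 6 had an unadjusted interaction p under 0.05, and each adjusted p was 0.993. They were picked for a low p in some tissue on these same arrays, which favours a low interaction p. The count therefore decides nothing.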
